A study of Gallus gallus with 2 samples.

How the data were processed

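The series compared the diet of broiler chickens, garlic metabolites against no supplement, in total RNA of intestinal IEL at day 14. RNA was extracted with Trizol and amplified and labelled with Cy3 or Cy5 by in vitro transcription, per the labels' protocols. Both arrays of the series were used, and per the file headers they lie on the same slide.

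The scanner files hold, for each spot and channel, mean and local background intensity on a linear scale, which the authors extracted with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The processed intensity of each channel was spatially detrended and dye-normalized by that program, with LOWESS settings listed, per the file headers. The deposited log10 ratio of each spot is that of the red over the green processed signal, with surrogate values where a channel was too dim, which touched 48.9% of the gene spots on array 1 and 45.3% on array 2. The deposited p-value of each log ratio comes from the program's error model for 1 array, per the file headers. The series value table, deposited by the authors, was matched by probe name. It equalled the log10 ratio of array 1 (r = 1) and that of array 2 with its sign turned (r = -1), so it holds garlic over control on a log10 scale without further centring. The median of each of its columns was 0. The direction of every ratio was taken from the dyes in the labels. Before turning, the deposited log ratios of the arrays correlated at -0.47 across gene spots.

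Each array has 43451 spots, of which 1417 are controls. Background was corrected with limma 3.58.1 in R 4.3.3 by normexp with an offset of 50, fitted on all spots. Each array was then normalized by global loess with control spots at weight 0. Control spots were left out, and so were spots marked as outliers, 75 gene spots on array 1 and 294 on array 2. The offset pulls ratios of dim genes towards 0. Ratios were turned to garlic over control. The 42034 gene probes were named through the reference table of the assembly bGalGal1.mat.broiler.GRCg7b, used for names and gene lengths only, since the headers name the build galGal2. By accession 5263 probes were matched, by gene number 3774, by symbol 888 and by synonym 303. Another 15 kept the symbol of the file over a gene number, and 31791 kept the file's name. Matched probes carry the reference's name, and the others keep that of the array design, which can be old. The array's PNLIP probe was thereby named PNLIPRP1 and is not a measured member of the fixed pancreatic list, which holds PNLIP. Where several probes carried the same name, as for 618 tested genes, the probe with the highest mean log2 intensity was used. A gene was tested if it was measured on both arrays and well above background in the garlic channel of both or in the control channel of both. That left 16751 of 39923 genes, 5706 of them with a gene symbol.

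The mean of the 2 dye-oriented log2 ratios was tested per gene with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each gene has 1 residual degree of freedom, to which the prior added 3.50 (prior SD 0.24). A dye term would leave none, so a gene's own dye bias stays in its residual and cancels in its mean. Values are given as mean ± SD over n = 2 arrays. For a gene not well above background in 1 group on both arrays a bound was worked out. For the genes named it equalled the fold of the mean log2 ratio, so the mean is given. That bound sets the mean log2 signal of the bright group against that of the dim group, taking per array the higher of its own signal and the lowest signal of any probe well above background in that channel, after loess and Aquantile normalization.

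The rules below were set before the data were examined. Genes named are the 12 with the largest positive and the 12 with the largest negative mean log2 ratio among called genes that carry a symbol and move the same way on both arrays. From each of 24 fixed gene lists, up to 4 called members with the largest moderated t are named, or, where none was called, the 2 members with the largest t, as values only. A few genes that these rules picked are not described here, though they stay in every count and list value. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Fry asks whether a list moves on balance in 1 direction. With an estimated correlation camera falls back on the 1 residual degree of freedom and has almost no power, so its outcome decides nothing. The 8 lists of cell markers cover T cells, cytotoxic cells, B cells, macrophages and heterophils, epithelium, red cells and thrombocytes, smooth muscle and stroma, and pancreas.

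The steps were tested on simulated spot intensities built from the fitted spread of this comparison. Of 200 changed genes among 16751, drawn from the brighter genes, all 200 were estimated in the right direction, and 4 unchanged genes were called. Of 50 genes per size, 39 were recovered at a log2 ratio of 2 and 37 at -2, against 1 at 1 and 0 at -1. With no gene changed, 0 were called, and 5.24% had an unadjusted p below 0.05. The simulated spread of each gene was drawn from the fitted prior, independently, without a dye shift and without a trend on brightness. That outcome was therefore largely built in. It checks the steps and does not show the error rate in the real data. With 3000 genes changed by 1.5 on the log2 scale, 2996 genes were called, of which 98 were unchanged. A list of 28 genes shifted by -0.5 was recovered by camera. In that run no other gene changed and genes varied independently. It therefore does not show what shift camera could detect among the real changes.

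Alternatives were other background corrections, processed signals, the series value table, median centring, Aquantile scaling, other filters on dim spots, the mean of all probes, other priors and thresholds, the program's own p-values, the ratios without turning array 2, a fold size of 1.5, and each array alone. Restricting the fit to genes with a symbol was added after the data were seen. A slide block was not fitted, since both arrays share a slide.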

Results

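RNA from the intestine of broiler chickens at day 14 of age was compared on 2 two-colour Agilent oligonucleotide arrays. The tissue is labelled intestinal IEL, the usual abbreviation for intraepithelial lymphocytes, the lymphocytes that lie between the epithelial cells of the gut. Each array held RNA of birds fed garlic metabolites in one channel and RNA of untreated control birds in the other. Array 1 carried the garlic RNA in Cy5 and the control RNA in Cy3, and array 2 carried them with the dyes exchanged. The labels call the arrays biological replicates and also call the second a dye exchange of the first. They were counted as 2 replicates, and if they shared RNA the p-values measure technical spread alone. Each array held 42034 gene spots. On array 1, 49.4% of them were well above background in the garlic channel and 37.2% in the control channel. On array 2 the shares were 39.4% for garlic and 53.6% for control, so the Cy5 channel showed more spots above background on both arrays. No gene spot was saturated. The small number of arrays limits the precision of every value.

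The comparison asks how the garlic supplement altered gene expression in this gut preparation, in a series whose title concerns resistance to the intestinal parasite Eimeria acervulina. The labels of these samples name no infection. With garlic, 611 genes were higher and 227 were lower among 16751 tested genes (limma, adjusted p below 0.05). All 838 moved the same way on both arrays, which the test itself requires with 2 arrays, so it is no separate sign of agreement. ASS1 and GLUL, which encode enzymes of arginine and glutamine synthesis, were among the highest of those with a gene symbol. GSTT1, a glutathione S-transferase, and ISX, an intestine-specific homeobox factor, were among the lowest of these. The called genes changed by at least 1.91-fold, with a median of 2.58-fold. The log2 ratios of the arrays correlated across genes with Pearson r = 0.74 and Spearman rho = 0.71, where genes are not independent replicates. Regardless of any test, 577 genes were at least 2-fold higher and 147 at least 2-fold lower on both arrays, against 2 genes that were 2-fold changed in opposite directions. The log2 ratios were more widely spread on array 1 (SD 0.73) than on array 2 (SD 0.54).

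**Figure D1:**
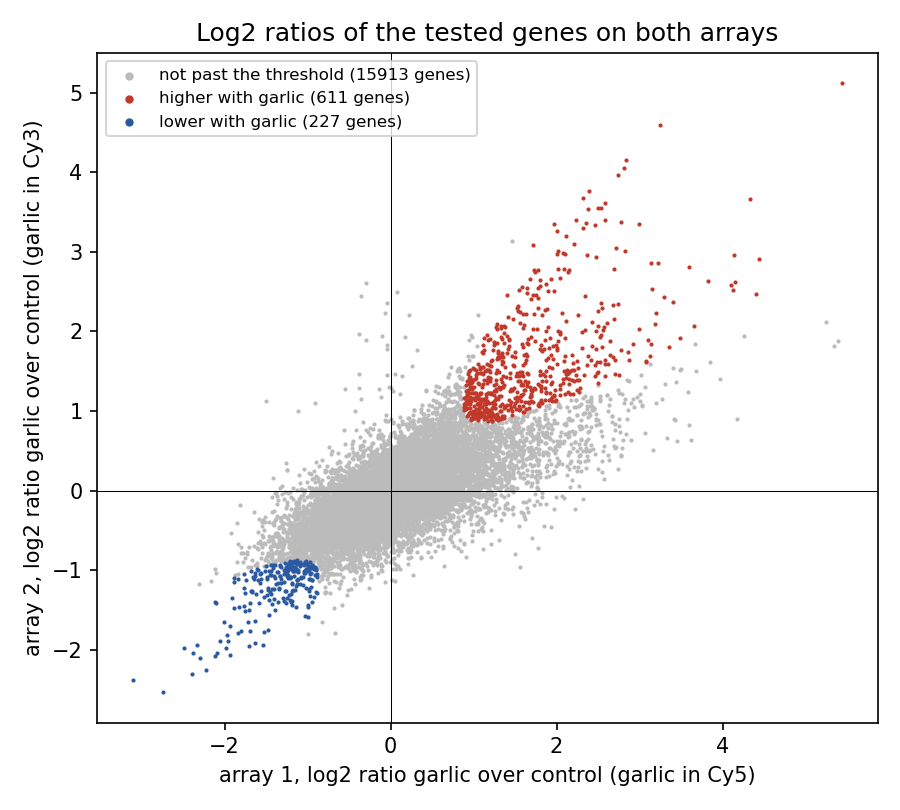
Log2 ratio of garlic over control for each of the 16751 tested genes on array 1 (x axis, garlic in Cy5) and array 2 (y axis, garlic in Cy3), each point being 1 gene. The 611 genes called higher (red) lie in the upper right and the 227 called lower (blue) in the lower left, and the correlation across genes was 0.74.

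The calls lay close to the threshold, with adjusted p between 0.0334 and 0.0499, and their number moved with the processing. Feature Extraction's own processed signals gave 1102 higher and 777 lower, median centring without loess left 1 gene, higher, and testing all 39923 measured genes without a filter on dim spots left none, with 7477 at an unadjusted p below 0.05. Median centring alone left the median log2 ratio of the tested genes at 0.42 on array 1 and -1.24 on array 2. All ratios here are after loess, which removes that shift, and are relative to the bulk of genes of like brightness.

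Of the 611 genes called higher, 189 carried a gene symbol. The 12 with the largest mean log2 ratio had adjusted p between 0.0365 and 0.0468. ASS1, argininosuccinate synthase, which makes the precursor of arginine from citrulline and aspartate, had a mean log2 ratio of 3.00 ± 0.20 (SD, n = 2), or 7.99-fold. GLUL, glutamine synthetase, reached 2.58 ± 1.1, with 3.36 on array 1 and 1.80 on array 2. PDPR, the regulatory subunit of pyruvate dehydrogenase phosphatase, reached 2.80 ± 0.69. Among signalling ligands, GDF2, also known as bone morphogenetic protein 9, reached 2.84 ± 0.44. WNT4 was at 2.51 ± 0.70, or 5.71-fold, and was not well above background in the control channel of either array. ITGB1BP2, the integrin-binding muscle protein melusin, had the largest mean of these, 3.1 ± 0.73. THSD7A, a membrane protein with thrombospondin domains, reached 2.92 ± 0.13, and ARC, an activity-regulated cytoskeletal protein best known from neurons, 2.71 ± 0.33. CBX1, heterochromatin protein 1 beta, reached 2.70 ± 1.12. ZZEF1 reached 2.88 ± 0.73 and PLEKHQ1 2.90 ± 0.61. ITGB1BP2, PLEKHQ1 and PDPR were well above background in the control channel of 1 of the 2 arrays. THSD7A, PLEKHQ1 and PDPR each have another probe on the array, which did not pass the filter on dim or outlier spots.

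Of the 227 genes called lower, 87 carried a gene symbol, and the 12 with the largest decrease had adjusted p between 0.0365 and 0.0473. PNLIPRP1, a pancreatic lipase related protein, had the lowest mean log2 ratio of these, -2.21 ± 0.24 (SD, n = 2), or 4.63-fold lower with garlic. OIT3, a zona pellucida domain protein best known from liver, was at -2.06 ± 0.03. OSGIN1, an oxidative stress induced growth inhibitor, was at -1.89 ± 0.11, and GSTT1, of the theta class, at -1.69 ± 0.05. ISX, which limits vitamin A uptake, was at -1.52 ± 0.33. PRKAG2, a gamma subunit of the energy sensor AMP-activated protein kinase, was at -1.63 ± 0.40. CREBL2, a leucine zipper factor, was at -1.64 ± 0.17. MATN2, a matrix protein, was at -1.55 ± 0.20, and its other measured probe at -0.53. RCN2, a calcium-binding protein of the endoplasmic reticulum, was at -1.5 ± 0.38, P3H3, a collagen prolyl hydroxylase, at -1.47 ± 0.30, and CCZ1, a protein of endosome and lysosome traffic, at -1.48 ± 0.51. P3H3 was well above background in the garlic channel of 1 of the 2 arrays. All genes named in this and the preceding paragraph but CCZ1 also passed with Feature Extraction's processed signals.

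**Figure D2:**
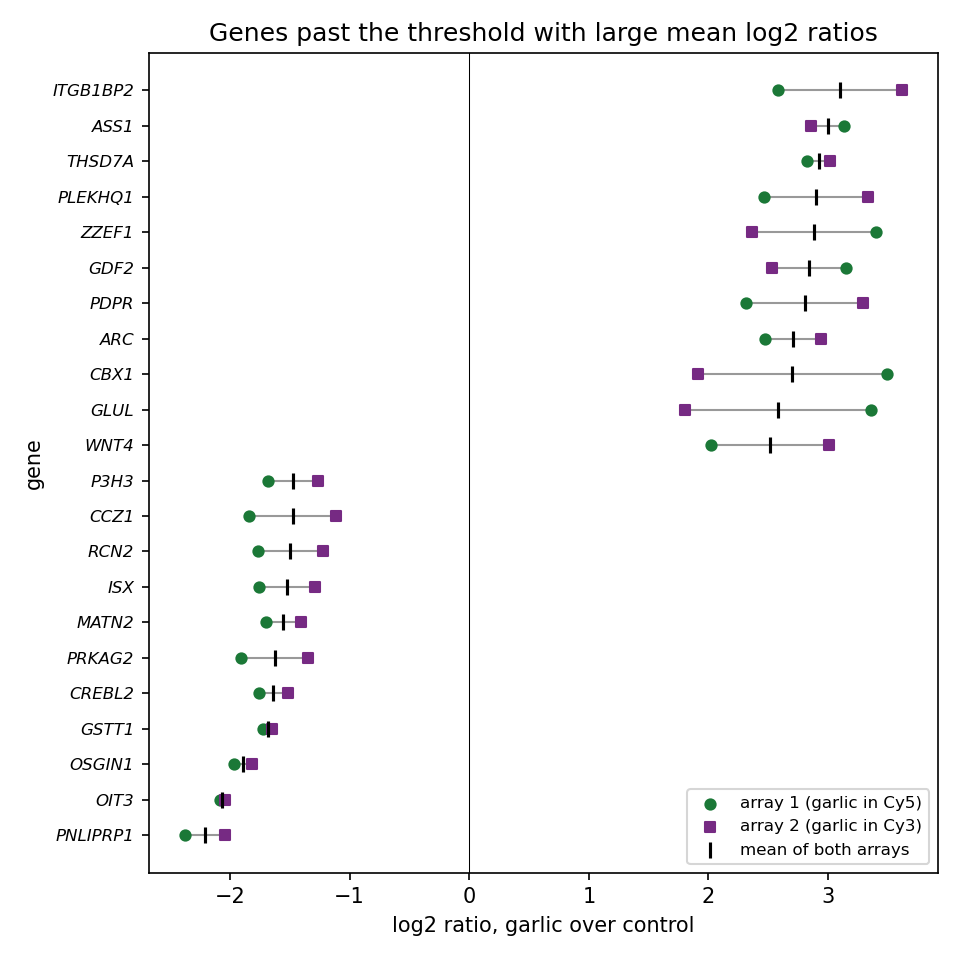
Log2 ratio of garlic over control (x axis) of 11 genes called higher and 11 called lower, from the 12 with a gene symbol and the largest mean in each direction (y axis), with array 1 as circles, array 2 as squares and the mean as a bar. The means run from 3.1 for ITGB1BP2 to -2.21 for PNLIPRP1. No gene has arrays on opposite sides of 0, which the rule for choosing them required.

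Of the immune pathway lists, the inflammatory cytokine and chemokine list lay lowest. Without the filter on dim spots it did not (-0.07, against -0.10 for the toll-like receptor list). Its 14 measured members had a median log2 ratio of -0.37 on array 1 and -0.45 on array 2. None passed over all genes, and 4 were lower when adjusted over the list alone. Among all 16751 tested genes 5267 had an unadjusted p below 0.05 (limma). Counts adjusted over a list alone, here and below, therefore do not by themselves set a list apart from other genes. CCL20, a chemokine of the gut mucosa, was at -0.97 ± 0.21 (SD, n = 2) and NOS2, inducible nitric oxide synthase, at -0.95 ± 0.21, the latter well above background in the garlic channel of 1 array. The list did not pass camera's test (adjusted p = 0.243). With an estimated correlation, which has almost no power here, camera's adjusted p was 0.857. Of 21 toll-like receptor and NF-kappaB genes, NFKBIZ, an inducible regulator of NF-kappaB target genes, fell by 1.40 ± 0.51, the other 20 did not pass, and none passed when adjusted over the list alone. That list's medians were -0.20 on both arrays (camera adjusted p = 0.251). Among 15 T helper cytokine and regulatory genes, GATA3, the lineage factor of type 2 helper T cells, rose by 1.11 ± 0.15 and SOCS3, an inhibitor of cytokine signalling, fell by 1.02 ± 0.02. When adjusted over the list alone, 2 of the 15 were higher and 1 lower. With Feature Extraction's processed signals NFKBIZ, GATA3 and SOCS3 did not pass, while NOS2, lower, and IFIH1, higher, did. None of 22 interferon response genes passed, and 3 were higher when adjusted over the list alone. IFIH1, a sensor of viral RNA, was at 0.85 ± 0.13, but its other measured probes were at 0.06 and -0.42. ZNFX1 was at 0.82 ± 0.13, with its other measured probes at 0.51 and 0.23. None of 9 antigen presentation genes passed either way, with DMB2, an MHC class II chaperone chain, at 0.90 ± 0.49 and PDIA3 at 0.68 ± 0.35.

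Most markers of the cell types that the preparation could hold were not called, as held for all tested genes, of which 838 of 16751 were. None of 13 T cell markers passed over all genes or when adjusted over the list alone. CD247, the zeta chain of the T cell receptor complex, was at 0.96 ± 0.66 (SD, n = 2) and CD3E at -0.54 ± 0.18. Of 5 cytotoxic and natural killer cell genes, XCL1, the chemokine lymphotactin, fell by 1.33 ± 0.32, which also held when adjusted over the list alone but not with processed signals. None of 6 B cell genes passed over all genes and 2 were higher when adjusted over the list alone, with CD79B at 0.96 ± 0.42 and BCL11A at 0.96 ± 0.45. None of 9 macrophage, dendritic cell and heterophil genes passed, and 1 was lower when adjusted over the list alone. CD83 was at -1.1 ± 0.33 and C1QB at 0.56 ± 0.22. With processed signals CD79B, higher, and CD83, lower, passed. The 25 measured enterocyte and other epithelial genes had medians of 0.80 on array 1 and 0.16 on array 2. None passed over all genes and 4 were higher when adjusted over the list alone. MEP1B, the brush border protease meprin beta, was at 1.1 ± 0.31 with its other measured probe at 0.54, and MTTP, which loads lipid onto lipoproteins, at 0.83 ± 0.21. That list had the lowest camera p (0.0045, adjusted p = 0.103). With an estimated correlation, which has almost no power here, camera's p was 0.523.

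Of 7 red cell and thrombocyte genes none passed over all genes and 2 were higher when adjusted over the list alone. HBA1, an alpha globin, was at 3.85 on array 1 and 1.62 on array 2 (adjusted p = 0.0633), and its other probe did not pass the filter on dim or outlier spots. HBE1, another globin, was at 0.76 ± 0.17 without passing (adjusted p = 0.069), though it passed with processed signals. HBE1 was not well above background in the control channel of either array. The smooth muscle and stroma list had 3 measured members and was not tested as a list. None passed over all genes and 1 was higher when adjusted over the list alone. PECAM1 was at 0.90 ± 0.19 (SD, n = 2) with its other measured probe at 0.01, and ACTG2 was at 0.16 ± 0.16. The 11 measured pancreatic genes moved apart. Of the 3 that fell, AMY2A, an amylase, fell by 1.26 ± 0.14 and CTRC, a chymotrypsin, by 0.93 ± 0.01, and CELA1, an elastase, rose by 1.03 ± 0.11, and none of these 3 named genes passed with processed signals. When adjusted over the list alone, 6 were lower and 3 higher. The medians of this list were -0.85 and -0.75 (camera adjusted p = 0.255).

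In the metabolic lists, single genes passed and no list did. Of 19 genes of fatty acid oxidation and ketogenesis, 2 fell, among them UCP3, a mitochondrial carrier, by 1.04 ± 0.21 (SD, n = 2), which was well above background in the garlic channel of 1 array. When adjusted over the list alone, 3 were lower. None of 17 sterol and fatty acid synthesis genes passed, and 3 were higher when adjusted over the list alone. Of 25 antioxidant and glutathione genes OSGIN1 fell, and of 31 xenobiotic metabolism genes GSTT1 fell, each the only member past the threshold over all genes or when adjusted over its list alone. Of 11 genes of sulfur amino acid and sulfide metabolism, PAPSS1, which makes the activated sulfate donor of sulfotransferases, rose by 1.67 ± 0.38, or 3.19-fold (adjusted p = 0.039). PAPSS1 was not well above background in the control channel of either array. When adjusted over that list alone, 1 gene was higher and 1 lower. None of 28 respiratory chain genes passed either way, with NDUFA5 at -1.55 ± 0.80 and NDUFB4 at -0.75 ± 0.01.

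In the lists of barrier, stress and growth genes, TJP1, the tight junction scaffold ZO-1, rose by 0.99 ± 0.06 (SD, n = 2) and CLDN10, a claudin that forms ion channels between cells, fell by 1.25 ± 0.28, among 17 measured barrier genes. When adjusted over the list alone, 2 of these were higher and 3 lower, and CLDN10 did not pass with processed signals. Of 17 apoptosis genes, BIRC2, an inhibitor of apoptosis protein, fell by 1.37 ± 0.03, which held when adjusted over the list alone (list camera adjusted p = 0.243). None of 24 heat shock and endoplasmic reticulum stress genes passed over all genes, and 1 was higher and 2 lower when adjusted over the list alone. DNAJB9 was at -1.14 ± 0.47 and ASNS, asparagine synthetase, at -0.88 ± 0.20. None of 27 cell cycle genes passed either way, with E2F1 at 0.83 ± 0.42 and BIRC5 at -0.53 ± 0.16. Of 34 cytosolic ribosomal protein genes, RPL39L rose by 1.41 ± 0.40, and 2 were higher and 1 lower when adjusted over the list alone.

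**Figure D3:**
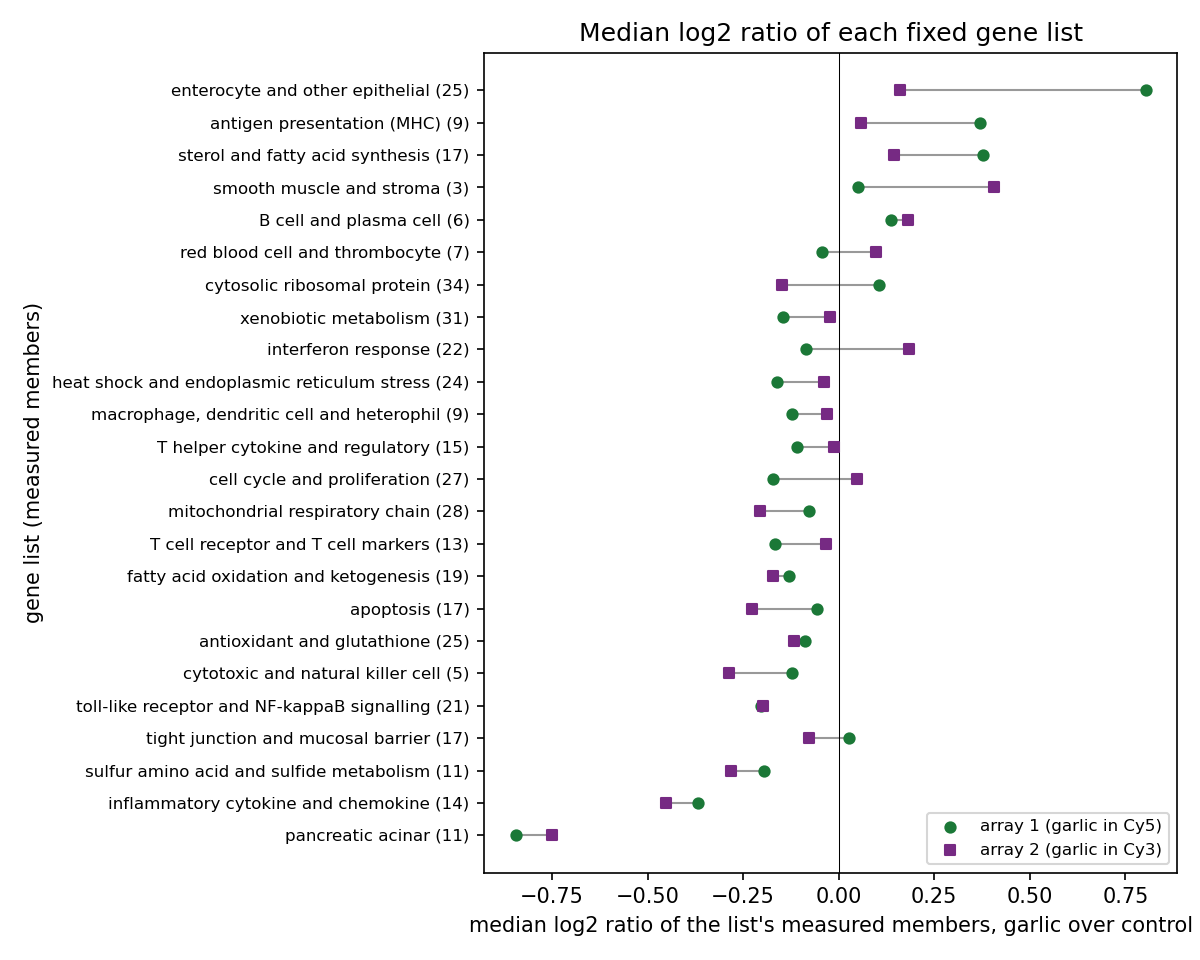
Median log2 ratio of garlic over control (x axis) of the measured members of each of the 24 fixed gene lists (y axis, measured members in brackets), with array 1 as circles and array 2 as squares. The pancreatic list lies lowest, at -0.85 and -0.75, the epithelial list has the largest value on array 1, 0.80, and no list passed camera's test.

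Across the 23 lists tested, camera gave adjusted p from 0.103 to 0.835, and 4 lists had an unadjusted p below 0.05. The lowest adjusted p with an estimated correlation was 0.857, which decides nothing, since 1 residual degree of freedom leaves almost no power. Medians were above 0 on both arrays in 4 of the tested lists and below 0 on both in 14. In the T cell, T helper and ribosomal protein lists the median was below 0, the mean above 0 and camera's direction down. In the interferon list the median was below 0, with the mean above 0 and camera's direction up. With median centring alone, where the median over all tested genes was -0.34, the medians of the epithelial, sterol, antigen presentation, B cell, red cell and smooth muscle lists turned negative. Relative to all genes, that of the B cell list alone did, at -0.11. Over all alternatives 11 lists changed the sign of their median at least once, the T cell, T helper, macrophage, barrier and ribosomal protein lists among them, so the sign of these small medians is not settled.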

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

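The number of calls was the least stable result. Against 838 genes, 1289 passed without background correction, 3574 with a normexp offset of 0, and 1879 with processed signals or the series value table. It was 3770 with an intensity trend in the prior, 3738 with trend and robust prior, 3069 at an adjusted p below 0.1, 5267 at an unadjusted p below 0.05 (2813 higher, 2454 lower) and 5209 by the program's own p-values on each array (2556 higher, 2653 lower), so the excess of higher calls shrank or turned. With median centring 1 passed, with the dye bias of each array left in. Without a filter on dim spots 0 passed, with 39923 genes tested, 7477 at an unadjusted p below 0.05 and a lowest adjusted p of 0.0838. A stricter filter that asks for both channels of both arrays and the mean of all probes kept the count within 1.5 times. Aquantile scaling changes intensities and not log ratios, so its unchanged count of 838 is no check. Fitted alone, an alternative added after the data were seen, genes with a symbol gave 559 calls (331 higher, 228 lower), against 276 of the same genes in the fit of all genes (189 higher, 87 lower). With array 2 not turned, limma called 0 genes, with 10 at an unadjusted p below 0.05. Of the 838 genes, 837 were also called without background correction, 838 with an offset of 0 and 644 with processed signals. The 2-fold count of 724 became 1824 with an offset of 0, 2992 with processed signals or the value table (36 in opposite directions), 213 with median centring (2115 in opposite directions), 2321 at 1.5-fold and 243 among genes with a symbol only, a smaller set. Array 1 alone gave 2341 genes at 2-fold and array 2 alone 982, and a single array gives no test and no correlation. The correlation of 0.74 was 0.24 with median centring and 0.68 without the filter. No list passed camera in the main setting, nor fry, nor camera with an estimated correlation, which has almost no power here. With median centring 3 passed (pancreatic, xenobiotic, respiratory chain). Without the filter, with the stricter filter, with the mean of all probes and with symbol genes only 1 passed, the epithelial list, whose adjusted p ranged from 0.0201 to 0.335 over the refits and was 0.857 with an estimated correlation and 0.458 with fry. The median of the T helper list turned positive without the filter and with the stricter filter, that of the T cell list with the stricter filter, that of the macrophage list without the filter, those of the barrier and ribosomal protein lists without the filter and with the mean of all probes, and that of the red cell list negative with the stricter filter and with processed signals. Of the 38 genes past the threshold that the naming rules picked, none changed direction under the 9 alternatives that refit all genes, where measured. Among these alternatives, Aquantile scaling keeps the log ratios and the value table repeats the processed signals, so neither adds a separate check. Of the 38 genes, 10 lost the threshold with processed signals and with the value table, and with median centring and without the filter all 38 did. Of the 26 picked genes not past the threshold, most passed with an offset of 0 and 5 with processed signals. Beyond what is stated, the cause was not tested. Signal over background limits the dim genes: 13225 genes were well above background in both channels of both arrays.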

Other observations

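Of the tests in this part, the second on loess, the odds ratio after the length trend was removed, that on genomic DNA and those on the pancreatic genes were chosen after the result was seen. The genes in this paragraph were also chosen after their values were seen and form no tested group. Among the genes called lower with garlic were CD36 at -0.93 ± 0.04, FABP3 at -1.15 ± 0.24 and SLC51B at -1.11 ± 0.17 (SD, n = 2). The gut peptide gene NTS, for neurotensin, was at -1.24 ± 0.24 and EDN2, for endothelin 2, at -1.16 ± 0.32. Regulators of chromatin and transcription were among the genes called higher, CTCF at 1.82 ± 0.01, NCOR1 at 1.81 ± 0.10, CEBPB at 1.53 ± 0.05 and ATRX at 1.04 ± 0.04. DSP, the desmosome protein desmoplakin, was at 1.23 ± 0.16 and SELP, the adhesion molecule P-selectin, at 1.26 ± 0.13.

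A group of structural RNAs, which work without being translated, was put together after the calls were seen and has no test as a group: of 9 tested probes, 8 had ratios above 0 on both arrays and 5 passed, among them small nucleolar RNA E2 at 3.67 ± 1.08, a small cytoplasmic RNA at 3.32 ± 1.13, 7SK at 2.02 ± 0.81 and 1 of 3 probes for mitochondrial ribosomal RNA at 1.64 ± 0.01 (SD, n = 2). The other 2 of these, at 2.00 ± 1.04 (adjusted p = 0.0588) and 0.76 ± 0.92 (adjusted p = 0.206), did not pass, nor did U4a small nuclear RNA at 5.24 and 2.13 (adjusted p = 0.0647) or U36b at 0.06 ± 0.13. A test of loess set beforehand met its own terms for loess as the source, with 4 of the 9 higher on both arrays and 2 of them at least 2-fold under median centring, but that scaling leaves the dye bias in, and of all 577 genes 2-fold higher on both arrays it kept 118, so the count decides nothing. A test chosen after that outcome took the mean of both dye orientations without loess, where the probes' median lay 1.83 above that of all genes. Dye bias cancels only in part in that mean, since the medians of all tested genes were 0.42 on array 1 and -1.24 on array 2. It therefore speaks only weakly against loess as the source. Genomic DNA would lift dim genes in general, yet genes well above background in garlic alone and in control alone stood at a ratio of 0.982 (215 and 219). Of 7 histone probes, for messages that lack a poly(A) tail, 0 were higher and 2 lower on both arrays, with a median of -0.0914. The others differed in sign between the arrays and several probes were dim, so this speaks only weakly against better copying of tailless RNA in general. The E2 sequence record also spans an intron of RPSA and the mitochondrial record also spans other mitochondrial genes, and what part the probes read was not examined. A different recovery of small or structured RNA and an effect of the diet stay open, and no biological explanation was tested.

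Longer genes were more often called higher: in the longest of 5 equal groups of the 5806 tested genes with a length in the reference assembly, 75 genes were higher and 12 lower, against 19 and 31 in the shortest group (Fisher's exact test for higher calls, two-sided, p = 1.5e-09, odds ratio 4.15, with genes not independent), though over all these genes length and log2 ratio were only weakly correlated (Spearman rho 0.04 on array 1 and 0.13 on array 2). Removing the length trend from each array left 96.8% of the higher calls (329 of 340, these genes fitted alone), which decides nothing, since the trend was small beside the calls (median change 0.08). After removal the odds ratio of a higher call was 2.18 (confidence interval 1.58 to 3.03), against 3.39 before, so an excess beyond the fitted trend remained. The lower calls went from 28 to 104 in the longest group and from 67 to 88 in the shortest. The longest group thus had more calls in both directions, and much of its lean towards higher calls was gone. Removal also raised the calls over all these genes, from 340 to 461 higher and from 254 to 396 lower. Counts and odds ratios before and after it therefore rest on different cutoffs, and their change cannot be put down to the trend alone. The longest group had the larger share of higher calls in 5 of 5 groups of probe brightness, against brightness as the explanation. RNA integrity and unspliced RNA may contribute and were not measured here, and an effect of the diet stays open.

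Pancreatic genes were mostly lower, 7 of 11 on both arrays, as was PNLIPRP1, while INS, the hormone among them, was higher on both arrays. Pancreatic tissue carried over into the control samples would raise all abundant acinar transcripts there. CPA1 and CELA1 were higher with garlic on both arrays, with a mean of 1.00, so carry-over alone does not account for them. They were picked for being higher, CPA1 did not pass (limma adjusted p = 0.0684), and CELA1 did not with processed signals. For the list as a whole they therefore decide nothing further. For the 7 lower members alone, with a median of -0.93, carry-over and an effect of the diet cannot be told apart, since these members were picked for being lower.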
